A study of Rattus norvegicus with 30 samples.

How the data were processed

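Purchased frozen hepatocytes of male Sprague Dawley rats were thawed, plated on collagen and overlaid with Matrigel. On day 3 of culture the wells received vehicle or WY-14643 at 8 µM or 200 µM, and RNA was taken 24 h or 48 h later. The labels list 30 arrays in 6 groups of 5 wells. They call the wells separate biological replicates and do not say whether the cells of different wells came from different animals, so every error and p given here measures the spread between wells. The vehicle wells are labelled 1% DMSO. The dosing stocks are described as concentrates in 1% DMSO, so the DMSO content of the treated medium is not certain from the labels. Each group appears once in each run of 6 consecutive array numbers, and the replicate numbers used here follow that order. The compound is 1 of 10, each run as a study of its own, and the others were not used here.

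The deposited values are intensity values, made by the authors with MAS5, which turns the probes of a probe set into a single signal. The version, the scaling target and the chip definition are not stated. The values were positive and linear, and their 2% trimmed mean lay between 1500.45 and 1500.7 on all 30 arrays, so each array had already been scaled to a common level. No further scaling was applied. Probe sets were joined to gene symbols with the platform annotation, dated 2016. Of 31099 probe sets 57 were controls, 20832 had 1 symbol, 436 had several and 9831 had none.

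Signals were taken as log2(signal + 16). A probe set was kept if its signal was above the 40th percentile of all values (281.361) in at least 5 of the 30 arrays, without regard to group. This left 21282 probe sets, of which 15629 had exactly 1 symbol. For the 3079 genes with more than 1 kept probe set, the probe set with the highest mean log2 signal was used, giving 11545 genes. No genome position was used.

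All 30 arrays were fitted together with 1 mean per group in limma 3.58.1 (R 4.3.3; lmFit, contrasts.fit and eBayes with a variance trend). The tests were two-sided and each contrast was adjusted by Benjamini-Hochberg over the 11545 genes, with a threshold of 0.05. The contrasts were each dose against the vehicle of its time, 200 µM against 8 µM at each time, the change of each dose's effect from 24 h to 48 h, and vehicle at 48 h against vehicle at 24 h. The words rose, fell and changed are used for genes below this threshold. Log2 fold changes carry their standard error from the fit, and signals carry the SD over n = 5 wells. The median standard error between 2 groups was 0.124.

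Gene lists were written from textbook knowledge before the data were examined, as were the contrasts, the rule for naming genes and the alternatives, apart from 4 named below. The 33 lists hold 648 genes, of which 544 were measured, 69 had no probe set with that symbol alone and 35 were below the signal filter. A listed gene carries an older symbol on the array list and is printed as Ccn2. Lists with at least 5 measured genes were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. Adjustment was over 32 lists and 9 contrasts, 288 tests. Beside each p stands the p of the same test with a correlation estimated for the list. Of 144 shifts called with the preset correlation, 33 were also called with the estimated one. The directional test of fry was also run. Counts given over the list alone are of genes that pass when adjustment corrects for the list's own members in place of all genes. Several genes stand in more than 1 list.

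Genes were named by rule. For each dose and time against vehicle these are the 10 largest rises and the 10 largest falls among changed genes whose 5 treated arrays all lay on 1 side of the 5 vehicle arrays. For every other contrast they are the 5 largest rises and 5 largest falls. For each list they are the 4 members with the largest moderated statistic in the treated contrasts. Not every one is printed. A further member of a list is given with its own adjusted p, and was chosen after its values were seen.

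The alternatives tried were pseudocounts of 1 and 64, quantile normalization, median centring, no filter and a filter at the 60th percentile (637.335, 8879 genes), the mean of a gene's probe sets, tests of probe sets, a fit of the 15 arrays of the time compared (for changes over time and the vehicle, of only the groups compared), a block for each run of 6 arrays, no variance trend, array weights, an added fold change of at least 1.5, and leaving out each array in turn. The 4 alternatives chosen after seeing the data all leave out replicate 4 of the 48 h vehicle group, from every contrast. They refit the counts, the counts after quantile normalization, the list tests with an estimated correlation, and the likeness of doses and times. Ratios of 3′ to 5′ control probe sets were compared between groups by two-sided exact permutation tests (252 splits), adjusted over 12 tests. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

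The fit was tested on 5 simulations per contrast, each with a known change in 200 of 11545 genes. At 8 µM and 24 h it called 63.2% of 1.5-fold and 94.0% of 3-fold changes, with 4.61% of calls false. At 200 µM and 48 h it called 59.2% and 91.6%, with 5.50% false. Real calls number 2853 to 4112 per treated contrast, so these are not their error rates. Signal over background and the number of arrays limit precision.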

Results

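Cultured rat hepatocytes were given WY-14643, also called pirinixic acid, a synthetic agonist of the nuclear receptor PPARα that makes peroxisomes multiply in rodent liver. RNA of single wells was read on an Affymetrix rat array, and each of 6 groups (vehicle, 8 µM and 200 µM, each at 24 h and 48 h) held n = 5 wells. The median signal of a probe set lay between 385 and 439 on 29 of the 30 arrays. On the array of 48 h vehicle replicate 4 it was 765. There 73.9% of probe sets were above the signal filter, against 57.9% to 61.2% on the others, and the median correlation across genes with its own group was 0.896, against 0.973 to 0.980. This array enters the spread behind every contrast, so the totals of genes and the calls of lists that it decides are also given without it, a choice made after seeing the data. The 3′ to 5′ signal ratio of β-actin can reflect RNA length and labelling. It was 2.86 ± 0.278 (SD, n = 5) in 24 h vehicle wells, 3.10 ± 0.214 at 8 µM and 3.31 ± 0.169 at 200 µM. At 48 h it was 2.61 ± 0.313, 3.26 ± 0.417 and 3.10 ± 0.201. By exact permutation p was 0.18, 0.024, 0.024 and 0.032 for the 4 treated groups against their vehicle, and no ratio passed after adjustment over 12 tests (lowest adjusted p = 0.114). Transcripts of Ppara itself were below the signal filter (210 ± 118 in 24 h vehicle wells).

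**Figure D1:**
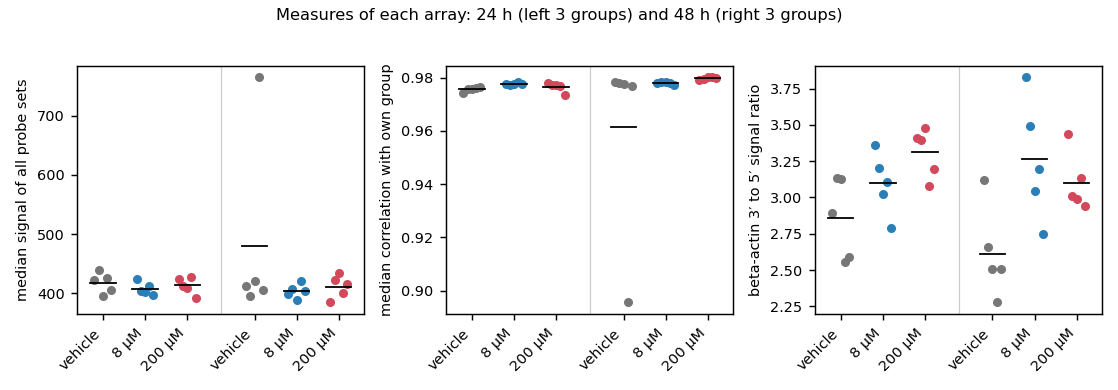
Each point is 1 array: its median signal, its median correlation across genes with the arrays of its own group, and its 3′ to 5′ signal ratio of β-actin, by group (24 h groups left, 48 h groups right, n = 5, lines are means). Replicate 4 of the 48 h vehicle group lies outside the ranges of the other 29 arrays in median signal and correlation.

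The first comparison asks which transcripts 8 µM WY-14643 changed within 24 h. Acot1, a cytosolic acyl-CoA thioesterase, went from a signal of 112 ± 47.7 in vehicle wells to 47071 ± 1192 (SD, n = 5), a log2 fold change of 8.61 ± 0.41 (SE). Ehhadh, the bifunctional enzyme of peroxisomal β-oxidation, rose by 5.25 ± 0.17. Cyp4a1, a fatty acid ω-hydroxylase, rose by 3.82 ± 0.09, and Pdk4, the kinase that shuts down pyruvate dehydrogenase, by 3.47 ± 0.09 (1.63 by its other probe set). The water and glycerol channel Aqp3 rose by 6.92 ± 0.23. The ectonucleotidase Entpd1 (4.44), the mitochondrial carrier Ucp2 (4.23), the keratin Krt79 (4.19), the fatty acid binding protein Fabp3 (4.16) and the kinase Nim1k (3.83) complete the 10 largest rises. The largest fall was that of Ccn2, connective tissue growth factor, by a log2 fold change of -3.56 ± 0.10, from 11935 ± 901 to 1000.4 ± 94.7. It was followed by Calml4 (-3.05), plasma kallikrein Klkb1 (-2.37), the peroxisomal hydroxyacid oxidase Hao2 (-2.33), Eva1c (-2.31), Steap4 (-2.26), the formin Diaph3 (-2.20), Sgsm2 (-2.14), vimentin (Vim, -2.10 ± 0.14) and the glucuronosyltransferase Ugt2b1 (-2.08). In all 1280 genes rose and 1590 fell, and 1031 of the 2870 changed by at least 1.5-fold. Low signals make the size of a change, and so its rank, depend on the pseudocount. Over all contrasts 49 changes of named genes moved by more than 0.5 log2 between pseudocounts of 1 and 64. Among them were rises of Acot1, Aqp3, Entpd1 (5.33 and 3.22 here), Ucp2, Krt79, Nim1k, Krtap1-5 and Slc25a34 (3.94 and 2.42 at 200 µM and 48 h). Falls among them were those of Eva1c (-3.04 and -1.82 at 200 µM and 24 h), Egr4, Calml4, Sgsm2, Slc17a2, Prr15l, Xpnpep2, Abca8a and Krt19. Where a named gene that changed against vehicle has other probe sets that were kept, these passed in the same direction in 102 of 168 comparisons and did not pass in 66, among them those of Crot, Cs, Cp, Il1r1, Rxrg, Cdkn1a, Ccnd1, Gclc, Hsph1 and Lyve1 in at least 1 contrast, and none passed in the opposite direction.

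Lists of fatty acid oxidation, peroxisomes and ketogenesis were called up at 8 µM and 24 h. All 18 measured genes of mitochondrial fatty acid oxidation rose (18 over the list alone, adjusted p = 4.4e-35, and 0.0054 with an estimated correlation). Examples are the carnitine palmitoyltransferases Cpt1a (2.83 ± 0.10, and 0.62 by its other probe set) and Cpt1b (3.37 ± 0.13) and the dehydrogenases Acadm (1.83 ± 0.07) and Acadvl (1.25 ± 0.05). Of 16 genes of peroxisomal β-oxidation 12 rose and 1 fell (12 and 1 over the list alone, adjusted p = 7.1e-17, and 0.038 with an estimated correlation). There were rises of Hacl1 (2.58 ± 0.07), Crot (1.73 ± 0.06) and Decr2 (1.53 ± 0.08). The member that fell was Acox2, an oxidase of branched chains and bile acid intermediates, at -1.41 (adjusted p = 1.1e-09). Of 15 genes that build peroxisomes 9 rose (11 over the list alone, adjusted p = 7.2e-08, and 0.014 with an estimated correlation). Examples are Pex11a (1.43 ± 0.06) and Pex16 (1.26 ± 0.09, and -0.19, adjusted p = 0.55, by its other probe set). Of 9 acyl-CoA thioesterases 8 rose (8 over the list alone, adjusted p = 8.5e-14, and 0.0095 with an estimated correlation). Acot4 was at 2.56 ± 0.11 and Acot2 at 2.35 ± 0.08. Of 12 genes of ketogenesis and fasting 7 rose (7 and 1 over the list alone, adjusted p = 4.5e-09, and 0.038 with an estimated correlation). Examples are Txnip (2.20 ± 0.07), Vnn1 (1.84 ± 0.09) and Creb3l3 (1.73 ± 0.09), and Igfbp1, a secreted binder of insulin-like growth factors, fell at -0.58 (adjusted p = 1.4e-06). Of 8 genes of microsomal ω-oxidation 3 rose, with Cyp4a3 at 2.98 ± 0.08, and 2 fell, with Cyp4f1 at -0.72 ± 0.14 (3 and 2 over the list alone, adjusted p = 0.029, and 0.23 with an estimated correlation). Their median was -0.10 and their mean 0.72, and without 48 h vehicle replicate 4 the list was no longer called (adjusted p = 0.067).

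The other lists called up at 8 µM and 24 h concern lipid, glucose and cholesterol metabolism and the respiratory chain. Of 16 genes of fatty acid uptake, binding and activation 9 rose and 2 fell (9 and 2 over the list alone, adjusted p = 4.1e-08, and 0.051 with an estimated correlation). There were rises of Acsl1 (3.02 ± 0.10), Fabp1 (2.22 ± 0.09) and Acsl3 (1.94 ± 0.10) and falls of Fabp7 at -0.40 (adjusted p = 0.0031) and Acsl4 at -0.42 (adjusted p = 6.1e-05). Of 16 genes of lipid droplets and lipolysis 9 rose and 1 fell (9 and 1 over the list alone, adjusted p = 2.5e-09, and 0.001 with an estimated correlation). Hilpda was at 2.66 ± 0.06, Mgll at 1.80 ± 0.09, Pnpla2 at 1.71 ± 0.08 and G0s2 at 1.78 ± 0.11. Pnpla2 and Mgll are lipases, whereas G0s2 and Hilpda restrain lipolysis, and the member that fell was Pnpla3 at -0.90 (adjusted p = 1.2e-05). Of 21 lipogenic genes 10 rose and 5 fell (10 and 6 over the list alone, adjusted p = 0.0033, and 0.24 with an estimated correlation). The rises included Fads1 (1.70 ± 0.13), Dgat1 (1.44 ± 0.07) and Me1 (1.30 ± 0.11), and the falls included the first enzymes of fatty acid synthesis, Acaca at -1.15 (adjusted p = 6.0e-11) and Acly at -0.68 (adjusted p = 1.4e-07). Of 17 genes of glucose and glycerol metabolism 9 rose and 7 fell (9 and 7 over the list alone, adjusted p = 5.7e-04, and 0.11 with an estimated correlation). The glycerol genes Gpd2, Gk and Aqp7 were at 2.82 ± 0.13, 2.81 ± 0.08 and 1.96 ± 0.07, and the glycolytic Pklr was at -1.05 (adjusted p = 5.9e-13). Of 21 genes of cholesterol synthesis 9 rose and 2 fell (10 and 2 over the list alone, adjusted p = 0.039, and 0.59 with an estimated correlation). Hsd17b7 was at 0.70 ± 0.09 and Sqle at -0.43 (adjusted p = 0.034). Its call ended after median centring (adjusted p = 0.17), with fry (adjusted p = 0.11) and without 24 h vehicle replicate 3 (adjusted p = 0.080) or 8 µM replicate 3 (adjusted p = 0.056) or 5 (adjusted p = 0.13). Of 25 genes of the respiratory chain and citrate cycle 7 rose (8 over the list alone, adjusted p = 0.0056, and 0.57 with an estimated correlation). Cs was at 0.72 ± 0.07 and Tfam at 0.61 ± 0.05, and the call ended with fry (adjusted p = 0.052).

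Lists of plasma proteins, bile acids, amino acid breakdown, hepatocyte identity, matrix and ER stress were called down at 8 µM and 24 h, none of them with an estimated correlation. Of 18 acute phase proteins 12 fell (14 over the list alone, adjusted p = 6.4e-06, and 0.3 with an estimated correlation). Itih4 was at -0.63 ± 0.08 and Cp at -0.60 ± 0.09. Of 23 genes of complement and coagulation 16 fell (16 over the list alone, adjusted p = 7.2e-08, and 0.11 with an estimated correlation). F5 was at -1.17 ± 0.10 and Serpinf2 at -1.04 (adjusted p = 4.7e-11). Of 16 genes of bile acid synthesis and transport 3 rose and 10 fell (3 and 11 over the list alone, adjusted p = 0.004, and 0.23 with an estimated correlation). The exporters Abcc2 and Abcb4 were at -1.27 ± 0.08 and -0.99 ± 0.08. Cyp27a1 was at -1.09 ± 0.07 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -2.06 (adjusted p = 3.2e-09). The members that rose were the bile acid receptor Nr1h4 (1.24 ± 0.08), Cyp8b1 at 0.43 (adjusted p = 0.0062) and Abcb11 at 0.26 (adjusted p = 0.0013). Of 28 genes of amino acid breakdown and the urea cycle 3 rose and 15 fell (3 and 16 over the list alone, adjusted p = 2.1e-04, and 0.37 with an estimated correlation). Mat1a was at -1.26 ± 0.10 and Cth at -1.22 ± 0.09, against a rise of Agxt, the peroxisomal alanine-glyoxylate aminotransferase of the rat, of 1.39 ± 0.09. Of 16 hepatocyte identity genes 1 rose and 7 fell (1 and 8 over the list alone, adjusted p = 0.0072, and 0.35 with an estimated correlation). Tat was at -1.54 ± 0.11, Onecut1 at -0.88 (adjusted p = 0.002) and Afm, which rose, at 0.26 ± 0.07, which did not pass after median centring (adjusted p = 0.20). Albumin was at -0.08 (adjusted p = 0.57). Of 17 genes of epithelial dedifferentiation and matrix 9 fell and 1 rose (1 and 9 over the list alone, adjusted p = 4.6e-04, and 0.29 with an estimated correlation). S100a6 was at -1.06 ± 0.11, Ccn1 at -0.92 ± 0.17 and Tgfb2, which rose, at 1.63 (adjusted p = 5.4e-04), while its other probe set was at -0.63 (adjusted p = 0.41). Of 23 genes of ER stress and the amino acid response 7 fell (7 over the list alone, adjusted p = 0.023, and 0.54 with an estimated correlation). The chaperone Hsp90b1 was at -0.73 ± 0.08 and Xbp1 at -0.58 ± 0.05, and the call ended after median centring (adjusted p = 0.12).

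The next comparison asks what 200 µM WY-14643 did at 24 h. Acot1 rose by 8.69 ± 0.41, Aqp3 by 5.98 ± 0.23, Ehhadh by 4.76 ± 0.17, Fabp3 by 4.21 ± 0.26, Ucp2 by 4.00 ± 0.25, Cyp4a1 by 3.86 ± 0.09 and Pdk4 by 3.66 ± 0.09. The other large rises were Nim1k (3.75), Krt79 (3.43) and Krtap1-5 (3.26). Ccn2 fell by a log2 fold change of -2.93 ± 0.10, followed by Eva1c (-2.55), Steap4 (-2.35), Klkb1 (-2.19), the transcription factor Egr4 (-2.18), Slc17a2 (-2.09), Prr15l (-2.08), Calml4 (-2.05), Sgsm2 (-1.99) and Vim (-1.97). In all 1344 genes rose and 1509 fell, and 915 of the 2853 changed by at least 1.5-fold.

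All 18 genes of mitochondrial fatty acid oxidation rose at 200 µM and 24 h (18 over the list alone, adjusted p = 4.8e-33, and 0.0054 with an estimated correlation). Cpt1a was at 2.96 ± 0.10 and Acadm at 1.82 ± 0.07. In peroxisomal β-oxidation 11 of 16 rose and 1, Acox2 at -0.96 (adjusted p = 2.8e-06), fell (11 and 1 over the list alone, adjusted p = 2.8e-15, and 0.045 with an estimated correlation). Of 15 peroxisome biogenesis genes 8 rose (11 over the list alone, adjusted p = 2.1e-06, and 0.031 with an estimated correlation). Pex11a was at 1.51 ± 0.06. Among thioesterases 8 of 9 rose (8 over the list alone, adjusted p = 3.0e-13, and 0.01 with an estimated correlation). Among ketogenesis and fasting genes 7 of 12 rose (7 over the list alone, adjusted p = 8.2e-10, and 0.03 with an estimated correlation). Vnn1 was at 2.15 ± 0.09 and Txnip at 2.15 ± 0.07. In ω-oxidation 3 of 8 rose and 2 fell (3 and 2 over the list alone, adjusted p = 0.01, and 0.17 with an estimated correlation). Cyp4a3 was at 3.03 ± 0.08 and Cyp4f1 at -0.68 ± 0.14 (adjusted p = 0.055 after median centring). In fatty acid uptake 9 of 16 rose and 1 fell (9 and 2 over the list alone, adjusted p = 7.2e-08, and 0.055 with an estimated correlation). Acsl1 was at 2.95 ± 0.10. In lipid droplets and lipolysis 9 of 16 rose and 1 fell (9 and 2 over the list alone, adjusted p = 3.6e-07, and 0.0031 with an estimated correlation). Hilpda was at 2.56 ± 0.06. In glucose and glycerol metabolism 9 of 17 rose and 6 fell (9 and 6 over the list alone, adjusted p = 0.0014, and 0.15 with an estimated correlation). Gpd2 was at 2.59 ± 0.13 and Gk at 2.57 ± 0.08. Lipogenesis (10 up and 7 down of 21, 10 and 7 over the list alone, adjusted p = 0.11), cholesterol synthesis (1 and 4 of 21, 1 and 4 over the list alone, adjusted p = 0.34) and the respiratory chain (5 up of 25, 2 over the list alone, adjusted p = 0.061) did not pass as lists. Lipogenesis did with fry (adjusted p = 0.0023), and the respiratory chain without the filter (adjusted p = 0.036) and without any of 5 single arrays, 48 h vehicle replicate 4 among them (adjusted p = 0.033 to 0.044), with 9 genes up and 3 of cholesterol synthesis up in the absence of that array.

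The same lists apart from ER stress were called down at 200 µM and 24 h too, none of them with an estimated correlation. Of 23 complement and coagulation genes 18 fell (19 over the list alone, adjusted p = 1.1e-09, and 0.062 with an estimated correlation). F5 was at -1.12 ± 0.10. Of 18 acute phase genes 8 fell (10 over the list alone, adjusted p = 1.7e-04, and 0.39 with an estimated correlation). Itih4 was at -0.58 ± 0.08. Of 16 hepatocyte identity genes 7 fell (7 over the list alone, adjusted p = 0.0043, and 0.31 with an estimated correlation). Tat was at -0.76 ± 0.11 and Foxa3 at -1.07 (adjusted p = 1.5e-09). Of 17 dedifferentiation and matrix genes 11 fell and 1 rose (1 and 12 over the list alone, adjusted p = 2.8e-05, and 0.21 with an estimated correlation). S100a6 was at -1.01 ± 0.11. In amino acid breakdown 4 of 28 rose and 15 fell (6 and 18 over the list alone, adjusted p = 0.0057, and 0.5 with an estimated correlation). Hal was at -1.49 (adjusted p = 6.3e-09) and Agxt at 1.25 ± 0.09. In bile acid synthesis and transport 3 of 16 rose and 10 fell (3 and 10 over the list alone, adjusted p = 0.041, and 0.39 with an estimated correlation). Cyp7a1 was at -1.69 (adjusted p = 2.1e-07) and Cyp27a1 at -0.72 ± 0.07, and the call ended without 24 h vehicle replicate 1 (adjusted p = 0.053), 3 (adjusted p = 0.053) or 5 (adjusted p = 0.051) or 200 µM replicate 2 (adjusted p = 0.061). Of 12 heat shock genes 5 rose (6 and 1 over the list alone, adjusted p = 0.044, and 0.41 with an estimated correlation). Dnaja1 was at 0.59 ± 0.07 and Hsph1 at 0.52 ± 0.08, and the call ended after median centring (adjusted p = 0.088) and without 24 h vehicle replicate 2 (adjusted p = 0.062) or 4 (adjusted p = 0.094) or 200 µM replicate 2 (adjusted p = 0.082), 3 (adjusted p = 0.063) or 5 (adjusted p = 0.082). In the ER stress and amino acid response 9 of 23 rose and 3 fell (9 and 4 over the list alone, adjusted p = 0.098), with Trib3 at 0.69 (adjusted p = 0.0023) and Xbp1 at -0.65 ± 0.05.

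The likeness of the doses and times was measured across genes, which are not independent replicates. At 24 h 991 genes rose and 1141 fell at both doses and 7 moved oppositely. The log2 fold changes of the doses correlated at r = 0.870 (covariance 0.174), against 0.501 for simulated groups without effect that share vehicle arrays. With 2 or 3 different vehicle arrays each r was 0.688 to 0.717 (0.153 to 0.157). At 48 h 1535 rose and 1556 fell at both doses and 14 moved oppositely, r was 0.896, against 0.499 simulated, and 0.581 to 0.691 with different vehicle arrays. Between 24 h and 48 h, which share no arrays, r was 0.768 at 8 µM and 0.745 at 200 µM, with 1069 and 1096 genes up and 1179 and 1105 down at both times and 10 and 6 moving oppositely. Among genes changed at both doses, the median absolute log2 fold change was 0.519 at 8 µM and 0.487 at 200 µM at 24 h, and 0.528 and 0.505 at 48 h.

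At 48 h the question is whether 8 µM kept acting. Acot1 rose by 7.73 ± 0.41 (8.40 without 48 h vehicle replicate 1, where its signal was 1624), Aqp3 by 7.33 ± 0.23, Fabp3 by 5.72 ± 0.26, Ehhadh by 5.56 ± 0.17, Nim1k by 4.72 ± 0.30 and the muscle form of carnitine palmitoyltransferase, Cpt1b, by 3.88 ± 0.13, in n = 5 wells each. Entpd1 (4.23), Krt79 (4.10), the protease Prss23 (3.83) and Lrrc39 (3.59) complete the 10 largest rises. Ccn2 fell by a log2 fold change of -4.18 ± 0.10 and the interleukin 1 decoy receptor Il1r2 by -4.04 ± 0.17. Further falls were those of Prr15l (-3.80), neuropeptide Y (Npy, -3.66), Abca8a (-3.31), Hao2 (-3.26), Kng2l1 (-3.22), the male-specific Cyp2c11 (-2.96), Klkb1 (-2.86) and Steap4 (-2.85). In all 1928 genes rose and 2184 fell, and 1637 of the 4112 changed by at least 1.5-fold. Median centring moves the median of all genes in this contrast to 0.129 log2, and to 0.119 at 200 µM, so small falls at 48 h depend on the scaling.

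At 8 µM and 48 h all 18 genes of mitochondrial fatty acid oxidation rose (18 over the list alone, adjusted p = 1.1e-30, and 0.0064 with an estimated correlation). Cpt1a was at 2.84 ± 0.10 and Acadm at 2.26 ± 0.07. In peroxisomal β-oxidation 13 of 16 rose and 1, Acox2 at -0.71 (adjusted p = 1.5e-04), fell (14 and 1 over the list alone, adjusted p = 1.5e-16, and 0.038 with an estimated correlation). Of 15 peroxisome biogenesis genes 11 rose (13 over the list alone, adjusted p = 8.0e-09, and 0.01 with an estimated correlation). Pex19 was at 1.13 ± 0.08. All 9 thioesterases rose (8 without 48 h vehicle replicate 4) (9 over the list alone, adjusted p = 1.1e-12, and 0.01 with an estimated correlation). Acot4 was at 2.62 ± 0.11. In fatty acid uptake 12 of 16 rose and 2 fell (13 and 2 over the list alone, adjusted p = 4.6e-10, and 0.03 with an estimated correlation). Fabp1 was at 3.55 ± 0.09. In lipid droplets and lipolysis 10 of 16 rose and 1, the lipase Lipe at -1.10 (adjusted p = 2.1e-05), fell (10 and 3 over the list alone, adjusted p = 3.7e-07, and 0.0031 with an estimated correlation). In lipogenesis 14 of 21 rose and 3 fell (14 and 5 over the list alone, adjusted p = 8.0e-08, and 0.037 with an estimated correlation). Fads1 was at 2.51 ± 0.13, Me1 at 2.00 ± 0.11 and Acaca at -0.81 (adjusted p = 8.2e-08). In cholesterol synthesis 15 of 21 rose and 1, the regulator Srebf2 at -0.43 ± 0.08 (adjusted p = 0.13 after median centring), fell (15 and 2 over the list alone, adjusted p = 2.2e-06, and 0.26 with an estimated correlation). Hsd17b7 was at 1.10 ± 0.09 and Sc5d at 0.64 ± 0.06. In ketogenesis and fasting 8 of 12 rose and 2 fell (8 and 2 over the list alone, adjusted p = 1.8e-07, and 0.055 with an estimated correlation). Pdk4 was at 3.50 ± 0.09 and the coactivator Ppargc1a at -0.80 (adjusted p = 0.001). In the respiratory chain 13 of 25 rose (15 over the list alone, adjusted p = 2.2e-06, and 0.35 with an estimated correlation). Sdha was at 0.50 ± 0.07. In glucose and glycerol metabolism 9 of 17 rose and 6 fell (9 and 6 over the list alone, adjusted p = 3.3e-04, and 0.093 with an estimated correlation). Aqp7 was at 2.94 ± 0.07. In ω-oxidation 3 of 8 rose and 2 fell (3 and 2 over the list alone, adjusted p = 0.045, and 0.27 with an estimated correlation). Cyp4a1 was at 3.21 ± 0.09. That call ended after quantile normalization (adjusted p = 0.090), with an array-set block (adjusted p = 0.053), and without 48 h vehicle replicate 3 (adjusted p = 0.053) or 4 (adjusted p = 0.092), 8 µM replicate 5 (adjusted p = 0.088) or 200 µM replicate 5 (adjusted p = 0.051).

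Acute phase genes were lower at 8 µM and 48 h: 13 of 18 fell (13 over the list alone, adjusted p = 8.8e-09, and 0.2 with an estimated correlation). A2m was at -2.08 ± 0.11, Cp at -1.45 ± 0.09, Itih4 at -1.38 ± 0.08 and Serpina3n at -1.14 ± 0.07. In complement and coagulation 14 of 23 fell and 2 rose (3 and 15 over the list alone, adjusted p = 8.8e-06, and 0.2 with an estimated correlation). C1s was at -1.58 ± 0.09, F5 at -1.46 ± 0.10 and C3 at -1.10 ± 0.10. In bile acid synthesis and transport 3 of 16 rose and 10 fell (3 and 10 over the list alone, adjusted p = 0.0065, and 0.26 with an estimated correlation). Abcc2 was at -1.62 ± 0.08, Abcb4 at -1.49 ± 0.08 and Cyp7a1 at -1.83 (adjusted p = 2.7e-08). In amino acid breakdown 5 of 28 rose (3 without 48 h vehicle replicate 4) and 14 fell (5 and 14 over the list alone, adjusted p = 0.0046, and 0.49 with an estimated correlation). Cth was at -1.55 ± 0.09. Among dedifferentiation and matrix genes 8 of 17 fell (8 over the list alone, adjusted p = 0.0021, and 0.35 with an estimated correlation). S100a6 was at -2.27 ± 0.11 and Vim at -1.92 ± 0.14. Among hepatocyte identity genes 1 of 16 rose and 9 fell (1 and 9 over the list alone, adjusted p = 0.028, and 0.42 with an estimated correlation). Ahsg was at -1.20 ± 0.08 and Afm at 0.89 ± 0.07, and the call ended after median centring (adjusted p = 0.051) and without 48 h vehicle replicate 5 (adjusted p = 0.076). In inflammatory signalling 1 of 14 rose and 7 fell (1 and 7 over the list alone, adjusted p = 0.017, and 0.069 with an estimated correlation). Cxcl1 was at -1.38 ± 0.15, Il1r1 at -0.97 ± 0.10 and Icam1 at -0.83 ± 0.12. The ER stress and amino acid response was mixed, with 6 up and 8 down of 23 (6 and 10 over the list alone, adjusted p = 0.59), Xbp1 at -0.94 ± 0.05 and Hsp90b1 at -0.85 ± 0.08.

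The same question was put to 200 µM at 48 h. Acot1 rose by 7.76 ± 0.41 (8.44 without 48 h vehicle replicate 1), Aqp3 by 6.70 ± 0.23, Fabp3 by 5.29 ± 0.26, Ehhadh by 5.15 ± 0.17, Pdk4 by 3.56 ± 0.09 and Cpt1b by 3.48 ± 0.13, with Nim1k (4.48), Ucp2 (3.34), the mitochondrial carrier Slc25a34 (3.33) and Krt79 (3.23) next. Ccn2 fell by a log2 fold change of -4.19 ± 0.10, Il1r2 by -3.49 ± 0.17 and Npy by -3.39 ± 0.08. Prr15l (-2.88), Klkb1 (-2.88), Steap4 (-2.71), Hao2 (-2.50), S100a6 (-2.46), Kng2l1 (-2.37) and the peptidase Xpnpep2 (-2.36) complete the 10 largest falls. In all 1936 genes rose and 1969 fell, and 1396 of the 3905 changed by at least 1.5-fold.

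At 200 µM and 48 h all 18 genes of mitochondrial fatty acid oxidation rose (18 over the list alone, adjusted p = 3.4e-29, and 0.0072 with an estimated correlation). In peroxisomal β-oxidation 13 of 16 rose and 1 fell (13 and 1 over the list alone, adjusted p = 7.2e-16, and 0.04 with an estimated correlation). Hacl1 was at 2.74 ± 0.07 and Crot at 1.93 ± 0.06. Peroxisome biogenesis rose in 9 of 15 (12 over the list alone, adjusted p = 2.0e-07, and 0.017 with an estimated correlation). Pex11a was at 1.62 ± 0.06. Thioesterases rose in 8 of 9 (8 over the list alone, adjusted p = 2.5e-12, and 0.012 with an estimated correlation). Acot2 was at 2.50 ± 0.08. In fatty acid uptake 12 of 16 rose and 2 fell (12 and 2 over the list alone, adjusted p = 8.8e-09, and 0.04 with an estimated correlation). Acsl3 was at 2.41 ± 0.10. In lipid droplets and lipolysis 8 of 16 rose and 1 fell (8 and 1 over the list alone, adjusted p = 6.7e-06, and 0.0054 with an estimated correlation). G0s2 was at 2.14 ± 0.11. In ketogenesis and fasting 7 of 12 rose and 1 fell (7 and 1 over the list alone, adjusted p = 1.1e-07, and 0.055 with an estimated correlation). Vnn1 was at 2.10 ± 0.09. In lipogenesis 14 of 21 rose and 4 fell (15 and 5 over the list alone, adjusted p = 1.1e-05, and 0.076 with an estimated correlation). Fads1 was at 1.98 ± 0.13 and Dgat1 at 1.24 ± 0.07. In glucose and glycerol metabolism 9 of 17 rose and 6 fell (9 and 6 over the list alone, adjusted p = 5.7e-04, and 0.11 with an estimated correlation). Gpd2 was at 2.75 ± 0.13. In the respiratory chain 12 of 25 rose (12 over the list alone, adjusted p = 2.0e-04, and 0.46 with an estimated correlation). Tfam was at 0.55 ± 0.05. In ω-oxidation 3 of 8 rose and 1 fell (4 and 1 over the list alone, adjusted p = 0.0085, and 0.16 with an estimated correlation). Cyp4a1 was at 3.16 ± 0.09. Cholesterol synthesis did not pass (5 up and 3 down of 21, or 3 and 7 without 48 h vehicle replicate 4, 5 and 4 over the list alone, adjusted p = 0.66).

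Acute phase genes fell in 13 of 18 at 200 µM and 48 h (13 over the list alone, adjusted p = 7.2e-08, and 0.22 with an estimated correlation). A2m was at -2.14 ± 0.11 and Serpina3n at -1.29 ± 0.07. Complement and coagulation genes fell in 15 of 23 (15 over the list alone, adjusted p = 7.9e-09, and 0.077 with an estimated correlation). C1s was at -1.40 ± 0.09 and Plg at -0.98 ± 0.08. Hepatocyte identity genes fell in 9 of 16 (9 over the list alone, adjusted p = 0.0011, and 0.25 with an estimated correlation). Ahsg was at -0.99 ± 0.08. Dedifferentiation and matrix genes fell in 10 of 17 (1 and 11 over the list alone, adjusted p = 1.7e-05, and 0.2 with an estimated correlation). Vim was at -1.99 ± 0.14 and Ccn1 at -1.44 ± 0.17. In the ER stress and amino acid response 10 of 23 rose and 2 fell (11 and 2 over the list alone, adjusted p = 0.0062, and 0.47 with an estimated correlation). Sdf2l1 was at 1.20 ± 0.10, Ddit3 at 1.21 (adjusted p = 9.4e-09) and Xbp1 at -1.08 ± 0.05. That call ended after quantile normalization (adjusted p = 0.059) and without 48 h vehicle replicate 4 (adjusted p = 0.093). Among nuclear receptors and partners 10 of 19 rose and 4 fell (10 and 4 over the list alone, adjusted p = 0.046, and 0.13 with an estimated correlation). The retinoid receptor Rxrg was at 1.22 ± 0.07, Esrra at 0.94 ± 0.13 and the pregnane X receptor Nr1i2 at 0.41 ± 0.06. That call ended after quantile normalization (adjusted p = 0.058), without the signal filter (adjusted p = 0.055), and without 48 h vehicle replicate 3 (adjusted p = 0.053) or 4 (adjusted p = 0.061), 8 µM replicate 5 (adjusted p = 0.053) or 200 µM replicate 2 (adjusted p = 0.052) or 5 (adjusted p = 0.058). Bile acid synthesis and transport (3 up and 9 down of 16, 3 and 9 over the list alone, adjusted p = 0.1) and amino acid breakdown (6 up and 14 down of 28, 6 and 14 over the list alone, adjusted p = 0.061) did not pass as lists. Both passed after quantile normalization (adjusted p = 0.036 and 0.0031), and without 48 h vehicle replicate 4 amino acid breakdown did (adjusted p = 0.0029).

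Markers of other liver cells were read in the same contrasts. Of 11 macrophage markers 4 fell at 200 µM and 48 h (4 over the list alone, adjusted p = 0.036, and 0.18 with an estimated correlation). C1qb was at -1.44 ± 0.35 (signal 87.7 ± 43.2 at 200 µM, below the filter value), Cd5l at -0.90 ± 0.19, Lyz2 at -0.81 ± 0.10 and C1qa at -0.59 ± 0.13. That call ended after quantile normalization (adjusted p = 0.12) and without 48 h vehicle replicate 3 (adjusted p = 0.053) or 4 (adjusted p = 0.086). At 8 µM and 24 h, 200 µM and 24 h, and 8 µM and 48 h the list was not called (adjusted p = 0.73, 0.24 and 0.7). Stellate cell and fibroblast markers were not called in any of the 4 contrasts, in the same order and then 200 µM at 48 h (adjusted p = 0.81, 0.52, 0.31 and 0.1, with 5 of 11 down in the last and 5 over the list alone; 2 without 48 h vehicle replicate 4). The last passed with fry (adjusted p = 6.6e-04) and after median centring (adjusted p = 0.030), and Acta2, smooth muscle actin, fell at each dose and time (-0.53, -1.24, -0.48 and -0.95; at 8 µM and 48 h adjusted p = 0.20 after median centring). Endothelial markers were not called either (adjusted p = 0.69, 0.68, 0.92 and 0.53, with 2 of 7 down in the last and 2 over the list alone). At 200 µM and 48 h Lyve1 was at -1.07 ± 0.18 and Tek at -0.86 (adjusted p = 0.015), and without 48 h vehicle replicate 4 Tek did not pass (adjusted p = 0.063) while Eng, at 0.33 (adjusted p = 0.15), did (adjusted p = 0.020). Pecam1, at -0.62 (adjusted p = 0.16), passed without 48 h vehicle replicate 2 (adjusted p = 0.0017). Of bile duct markers 3 were measured, too few for a list test: Krt19 was at -1.72 (adjusted p = 0.0097), -0.99 (adjusted p = 0.17), -2.55 (adjusted p = 1.2e-04) and -1.89 (adjusted p = 0.0034), Epcam at -0.20 (adjusted p = 0.055), which without 48 h vehicle replicate 4 was adjusted p = 5.8e-05, and Cldn7 at 0.17 (adjusted p = 0.82) at 200 µM and 48 h.

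The doses were then compared. Genes of ER stress and the amino acid response were higher at 200 µM: at 24 h 10 of 23 rose and 1 fell (15 and 1 over the list alone, adjusted p = 3.2e-15, and 0.038 with an estimated correlation). At 48 h 8 rose and 1 fell (11 and 2 over the list alone, adjusted p = 7.0e-12, and 0.065 with an estimated correlation). Sdf2l1 differed by 0.40 ± 0.10 and 1.67 ± 0.10, Hsp90b1 by 0.49 ± 0.08 and 0.75 ± 0.08, and Dnajc3 by 0.22 ± 0.06 and 0.64 ± 0.06, at 24 h and 48 h. Phgdh, the first enzyme of serine synthesis, was 0.97 ± 0.11 higher at 24 h, and Trib3 differed by 0.80 (adjusted p = 0.0039) and 0.55 (adjusted p = 0.057). Without 48 h vehicle replicate 4 the list was called with an estimated correlation at 48 h as well (adjusted p = 0.01). Cholesterol synthesis was lower at 200 µM, in 6 of 21 genes at 24 h (9 over the list alone, adjusted p = 1.7e-10, and 0.11 with an estimated correlation), and in 10 without 48 h vehicle replicate 4. At 48 h it was lower in 13 (17 over the list alone, adjusted p = 5.7e-23, and 0.016 with an estimated correlation). Hsd17b7 was at -0.68 ± 0.09 and -0.65 ± 0.09 and Msmo1 at -0.41 ± 0.09 and -0.55 ± 0.09. Lipogenesis was lower in 5 of 21 at 24 h (5 over the list alone, adjusted p = 3.1e-05, and 0.093 with an estimated correlation). At 48 h 7 were lower (9 over the list alone, adjusted p = 2.1e-06, and 0.055 with an estimated correlation). Fads1 was at -0.48 ± 0.13 and -0.53 ± 0.13. Lipid droplets and lipolysis were lower in 3 of 16 at 24 h (3 over the list alone, adjusted p = 1.0e-04, and 0.01 with an estimated correlation). At 48 h the count was 1 (2 over the list alone, adjusted p = 0.0025, and 0.04 with an estimated correlation), and 3 without that array. Mgll was at -0.59 ± 0.09 and -0.60 ± 0.09.

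Bile acid genes were higher at 200 µM than at 8 µM, in 3 of 16 at 24 h (3 and 1 over the list alone, adjusted p = 0.0021, and 0.21 with an estimated correlation). At 48 h there were 5 (7 over the list alone, adjusted p = 5.7e-06, and 0.055 with an estimated correlation). Abcc2 was at 0.74 ± 0.08 and 0.95 ± 0.08. Amino acid breakdown was higher at 200 µM in 8 of 28 at 48 h and lower in 1 (10 and 1 over the list alone, adjusted p = 8.7e-04, and 0.42 with an estimated correlation), a call that fry did not make (adjusted p = 0.070). Cth was at 0.98 ± 0.09 and Mat1a at 0.92 ± 0.10. Macrophage markers were lower at 200 µM than at 8 µM at 48 h in 3 of 11 (3 over the list alone, adjusted p = 0.0014, and 0.038 with an estimated correlation). C1qb was at -1.46 ± 0.35, at signals of 87.7 ± 43.2 against 257 ± 70.7 whose means are below the filter value, so that its size is uncertain, C1qa at -0.56 ± 0.13 and Cd68 at -0.60 (adjusted p = 0.014), and without 48 h vehicle replicate 4 this was adjusted p = 0.058 with an estimated correlation. Single genes that were higher at 200 µM at 24 h were Insyn1 (1.59 ± 0.37), LOC100912188 (1.44 ± 0.14), Ugt2b1 (1.32 ± 0.12) and Mat1a (1.00 ± 0.10), and lower were Entpd1 (-2.62 ± 0.36), Tpbpa (-1.62 ± 0.46), Lmcd1 (-1.49 ± 0.15), Prss23 (-1.14 ± 0.19) and Plekhb1 (-0.998). At 48 h they were Phf1 (2.63), Trim66 (2.07), Slc13a2 (2.00), Abca8a (1.73) and Ugt2b1 (1.69), and Plek (-2.37), Entpd1 (-2.05), Gpr182 (-1.73), Cfd (-1.71) and Veph1 (-1.65). The call of Insyn1 ended without 8 µM 24 h replicate 5 (adjusted p = 0.051) and as the mean of its probe sets (adjusted p = 0.38), and that of Trim66 without 200 µM 48 h replicate 4 (adjusted p = 0.053). Tpbpa's ended without any of 9 of 11 arrays tried (adjusted p = 0.072 to 0.13), and Gpr182's without any of 8 of 11 (adjusted p = 0.051 to 0.099). At 24 h 161 genes were higher and 188 lower, at 48 h 261 and 292. Without 48 h vehicle replicate 4 the totals of 349 and 553 became 676 and 1037, although that array belongs to neither dose.

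With the preset correlation camera called further lists between the doses, none of them with an estimated correlation, given with their genes changed in that direction. At 24 h the further lists called lower at 200 µM were mitochondrial fatty acid oxidation, peroxisomal β-oxidation, glucose and glycerol metabolism, peroxisome biogenesis and the respiratory chain (2, 3, 3, 0 and 0 genes; adjusted p = 1.5e-04, 5.4e-04, 0.0041, 0.026 and 0.045), and those called higher were amino acid breakdown, xenobiotic cytochromes P450, heat shock genes and acute phase genes (4, 2, 1 and 0 genes; adjusted p = 0.0025, 0.036, 0.045 and 0.045) (adjusted p = 0.2 to 0.67 with an estimated correlation). At 48 h those lower were mitochondrial fatty acid oxidation, peroxisomal β-oxidation, fatty acid uptake, glucose and glycerol metabolism, the respiratory chain, lipoproteins, dedifferentiation and matrix genes, peroxisome biogenesis and oxidative stress genes (4, 2, 3, 4, 0, 2, 0, 2 and 2 genes; adjusted p = 1.8e-07, 1.9e-04, 0.004, 0.0051, 0.0083, 0.0083, 0.012, 0.024 and 0.034), and those higher were xenobiotic cytochromes P450, interferon genes, acute phase genes and inflammatory signalling (4, 1, 5 and 2 genes; adjusted p = 9.1e-06, 0.0021, 0.0052 and 0.02) (adjusted p = 0.076 to 0.58 with an estimated correlation). Some of these calls ended when 1 of 30 arrays was left out. At 24 h those of acute phase genes, heat shock genes, the respiratory chain and cytochromes P450 did so without any of 5, 7, 6 and 5 (highest adjusted p = 0.22). At 48 h those of matrix genes, inflammatory signalling, oxidative stress and peroxisome biogenesis did without any of 2, 1, 5 and 2 (highest adjusted p = 0.18). After median centring peroxisome biogenesis, acute phase and heat shock genes, the respiratory chain and cytochromes P450 at 24 h, and at 48 h the respiratory chain, matrix and oxidative stress genes, were no longer called (adjusted p = 0.055 to 0.18), nor after quantile normalization lipoproteins and oxidative stress at 48 h (adjusted p = 0.051 and 0.080). Leaving out 48 h vehicle replicate 4, complement and coagulation was called as well at 48 h (adjusted p = 0.04), and with an estimated correlation fatty acid uptake was (adjusted p = 0.01). More members passed then, such as 7 of mitochondrial fatty acid oxidation and 6 of peroxisomal β-oxidation lower at 48 h.

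**Figure D2:**
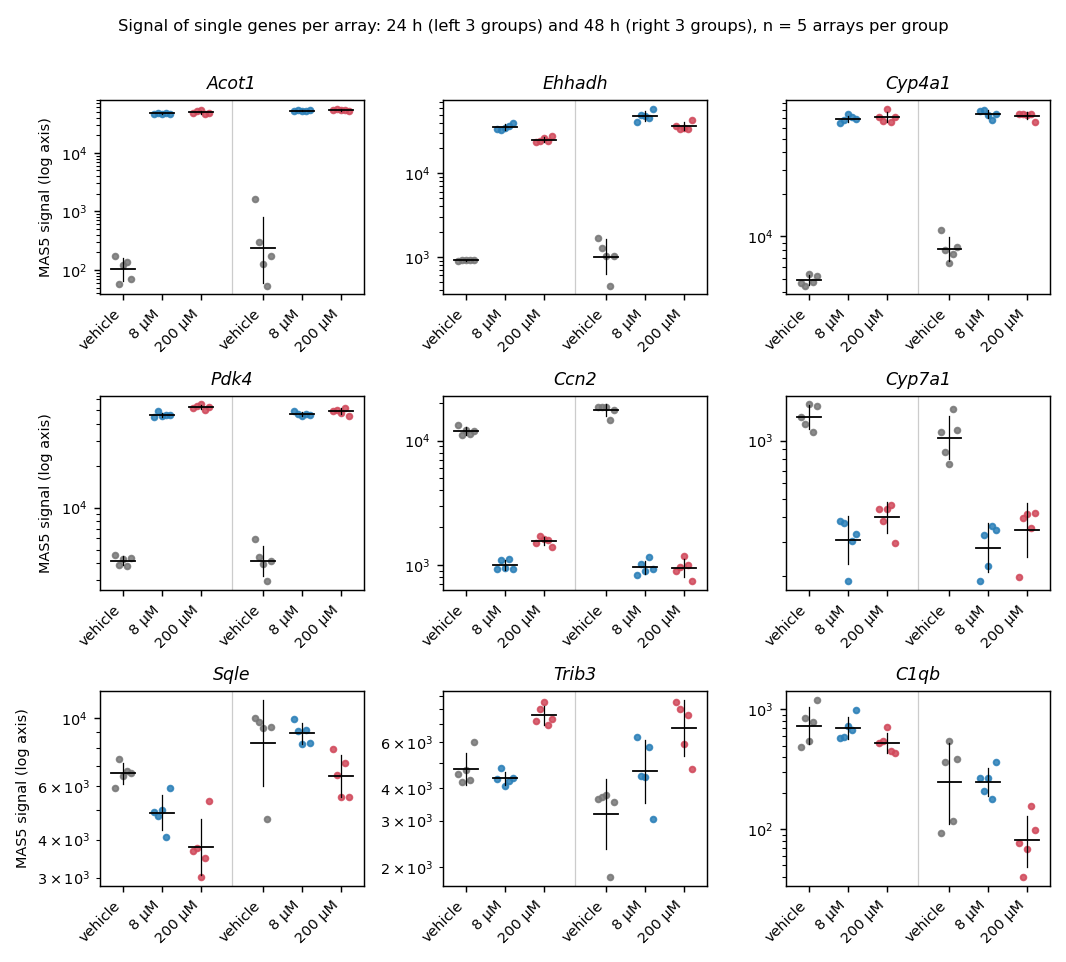
Signal of 9 genes on each array (log axis), by group, with the 24 h groups left and the 48 h groups right (n = 5; bars are the mean and SD of the log2 values). Acot1, Ehhadh, Cyp4a1 and Pdk4 rose and Ccn2 and Cyp7a1 fell at both doses, while Sqle, Trib3 and C1qb were chosen to show differences between 8 µM and 200 µM.

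Whether an effect changed between 24 h and 48 h was tested directly. The effect on lipogenesis was more positive at 48 h than at 24 h, in 10 of 21 genes at 8 µM (13 over the list alone, adjusted p = 1.5e-12, and 0.0072 with an estimated correlation). At 200 µM it was so in 7 (12 over the list alone, adjusted p = 5.0e-11, and 0.01 with an estimated correlation). Fads2 was at 1.18 (adjusted p = 0.033) and 1.27 ± 0.32. That on acute phase genes was more negative, in 7 of 18 at 8 µM (8 over the list alone, adjusted p = 5.9e-09, and 0.19 with an estimated correlation). At 200 µM it was so in 5 (7 over the list alone, adjusted p = 1.6e-07, and 0.23 with an estimated correlation), and 8 without 48 h vehicle replicate 4. A2m was at -1.65 ± 0.15 and -1.80 ± 0.15. Without 48 h vehicle replicate 4 both were also called with an estimated correlation (adjusted p = 0.01 and 0.011). The largest differences at 8 µM were more positive effects on Mapk13 (2.21), Dbp (2.17), Ppm1j (1.76), Eno2 (1.67) and Pla2g4b (1.61) and more negative ones on Spata19 (-3.09), Il1r2 (-2.998), Trim66 (-2.75), Prr15l (-2.39) and Cyp2c11 (-2.11). At 200 µM they were Dbp (1.53), Fabp1 (1.41), Fads2, Scd2 (1.25) and Spc24 (1.23), and Bcl2l15 (-2.49), Pdzk1ip1 (-2.46), Il1r2 (-2.42), Npy (-2.17) and Poll (-1.80). At 8 µM the calls of Pla2g4b, Spata19, Prr15l, Ppm1j and Trim66 ended without any of 15, 12, 10, 9 and 9 of the 20 arrays left out in turn (highest adjusted p = 0.099), and without 48 h vehicle replicate 4 Spata19 was at -2.49 (adjusted p = 0.061). At 200 µM those of Poll, Dbp, Bcl2l15 and Fads2 ended without any of 11, 8, 4 and 1 of 20 (highest adjusted p = 0.082). In all 335 effects differed at 8 µM (193 more positive and 142 more negative at 48 h) and 278 at 200 µM (150 and 128). Without that array the totals were 582 (270 and 312) and 488 (220 and 268), with the balance of directions reversed, and after median centring 42 and 28.

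Further lists were called with the preset correlation alone, given with their genes changed in that direction. At 8 µM the effect on cholesterol synthesis, mitochondrial fatty acid oxidation, fatty acid uptake, peroxisomal β-oxidation, oxidative stress genes, the respiratory chain and peroxisome biogenesis (2, 4, 5, 2, 5, 2 and 0 genes; adjusted p = 7.1e-08, 1.1e-06, 2.1e-06, 2.0e-05, 5.9e-05, 2.9e-04 and 0.016) was more positive at 48 h, and that on interferon genes and xenobiotic cytochromes P450 (0 and 3 genes; adjusted p = 0.0089 and 0.0098) more negative (adjusted p = 0.089 to 0.47 with an estimated correlation). At 200 µM it was more positive on peroxisomal β-oxidation, mitochondrial fatty acid oxidation, oxidative stress genes, fatty acid uptake, the respiratory chain, peroxisome biogenesis, cholesterol synthesis and conjugation and drug transport (2, 1, 3, 2, 2, 0, 0 and 1 genes; adjusted p = 9.7e-05, 2.6e-04, 3.5e-04, 6.7e-04, 0.0017, 0.022, 0.039 and 0.043), and more negative on dedifferentiation and matrix genes and complement and coagulation (2 and 4 genes; adjusted p = 0.01 and 0.027) (adjusted p = 0.23 to 0.59 with an estimated correlation). If 48 h vehicle replicate 4 was left out, peroxisome biogenesis and the respiratory chain were no longer called at 8 µM (adjusted p = 0.065 and 0.069) or 200 µM (adjusted p = 0.1 and 0.31), nor were cholesterol synthesis and conjugation at 200 µM (adjusted p = 0.7 and 0.82). Ketogenesis and fasting was then called at both doses (adjusted p = 0.04 and 0.0023), complement and matrix genes at 8 µM too (adjusted p = 0.004 and 0.031), and lipoproteins and hepatocyte identity at 200 µM (adjusted p = 0.016 and 0.0011).

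Vehicle wells at 48 h were compared with those at 24 h and differ in time in culture and in vehicle. Xenobiotic cytochromes P450 fell in 13 of 21 (15 over the list alone, adjusted p = 1.5e-21, and 0.0054 with an estimated correlation). Cyp2c13 was at -2.22 ± 0.11, Cyp3a2 at -2.12 (adjusted p = 6.3e-14) and Cyp1a2 at -1.09 ± 0.08. Complement and coagulation fell in 12 of 23 (15 over the list alone, adjusted p = 4.2e-10, and 0.055 with an estimated correlation). Lipoproteins fell in 7 of 19 (8 over the list alone, adjusted p = 1.1e-07, and 0.055 with an estimated correlation). Lcat was at -0.83 ± 0.09. Amino acid breakdown fell in 10 of 28 (11 over the list alone, adjusted p = 3.7e-07, and 0.23 with an estimated correlation). Macrophage markers fell in 5 of 11 (6 over the list alone, adjusted p = 0.0043, and 0.055 with an estimated correlation). C1qb was at -1.51 ± 0.35 and Cd5l at -0.92 ± 0.19. Acute phase genes fell in 9 of 18 and rose in 1 (1 and 14 over the list alone, adjusted p = 4.0e-08, and 0.21 with an estimated correlation). The lists called up were dedifferentiation and matrix genes (5 up of 17, adjusted p = 0.0083) and cholesterol synthesis (5 up and 3 down of 21, adjusted p = 0.036), and the others called down were hepatocyte identity genes, the respiratory chain, peroxisomal β-oxidation, interferon genes, ER stress genes, glucose and glycerol metabolism and bile acid genes (4, 5, 7, 5, 8, 3 and 3 genes; adjusted p = 4.5e-05, 5.9e-05, 1.4e-04, 3.1e-04, 0.0021, 0.026 and 0.049) (adjusted p = 0.16 to 0.58 with an estimated correlation). When 48 h vehicle replicate 4 was left out, peroxisomal β-oxidation, bile acid, glucose and ER stress genes were no longer called (adjusted p = 0.093, 0.24, 0.12 and 0.11), and thioesterases, ketogenesis and heat shock genes were (adjusted p = 0.02, 8.8e-04 and 0.047), with 11 genes of cholesterol synthesis up and 5 of amino acid breakdown down. Tsx (2.47), Tgfb2 (2.37, and -0.28, adjusted p = 0.79, by its other probe set), Scamp5 (2.31), skeletal actin Acta1 (1.92) and Lad1 (1.92) rose most, and Serpina6 (-2.45), Il1rn (-2.41), Gstp3 (-2.34), Car3 (-2.26) and Cyp2c13 fell most. In all 515 genes rose and 624 fell. Without that array it was 697 and 536, so the balance turned, and after median centring, which moves the median of all genes to -0.125 log2, 90 rose and 210 fell.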

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

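Tests chosen after the result was seen are those of a mislabelled array, of the β-actin ratio, of fewer cells of all kinds other than hepatocytes, and of fewer macrophages alone.

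The array of 48 h vehicle replicate 4 stood apart from its group. A wrong label alone is argued against. The array's median correlation was 0.896 with its own group and at most 0.896 with another, below the 0.973 or more of the other 29. A wrong label beside another fault cannot be told apart. Background or scaling that keeps the order of the genes is argued against as the whole reason, since after quantile normalization its median correlation with its own group was 0.908 and that of the others at least 0.973. RNA of other liver cells cannot be told apart: the 29 markers of macrophages, stellate and endothelial cells, none of which another list holds, lay 0.0603 log2 above the other vehicle arrays of 48 h, within the range of random gene sets of like signal (-0.439 to 0.364, percentile 66.5). How many of these markers hepatocytes express was not measured here (the most abundant macrophage marker, Lyz2, had a signal of 9377 ± 518 in the 48 h vehicle wells), and no other biological explanation was tested, since the design gives none.

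Genes of ER stress and the amino acid response were higher at 200 µM than at 8 µM (adjusted p = 0.038 at 24 h and 0.065, not called, at 48 h with an estimated correlation). Scaling is argued against: after quantile normalization or median centring the list stayed called at both times at the preset correlation (lowest median 0.192 log2, highest adjusted p = 1.2e-09). With the β-actin 3′ to 5′ ratio in the fit the median was 0.243 at 24 h, 82.5% of 0.294 (95% interval over genes 72.4% to 107%). At 48 h it was 0.226, 105% of 0.215 (99.7% to 120%). RNA quality that follows this ratio stays open, since wells were not resampled. Against vehicle the list was called down at 8 µM and 24 h and up only at 200 µM and 48 h, there not without vehicle replicate 4. A rise at 200 µM, a fall at 8 µM or both may be proposed as hypotheses, found and tested on the same data. A difference in DMSO content, which the labels do not settle, stays open too.

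Macrophage markers were lower at 200 µM than at 8 µM at 48 h. Fewer of all cells other than hepatocytes cannot be told apart. The macrophage median minus that of the stellate and endothelial markers (-0.0936) was -0.275 log2 (95% interval over genes, not wells, -0.515 to 0.0836). Fewer macrophages alone cannot be told apart either, since 9 of 11 markers were below 0, in a range of -1.46 (C1qb, whose mean signals of 87.7 ± 43.2 and 257 ± 70.7 are below the filter value; the next lowest is Cd68 at -0.60) to 0.18, and 2, Lyz2 (0.18) and Aif1 (0.16), had intervals above the list median, where 2 would have argued against it had not the signal of Lyz2 been more than 4 times the median of the list. A lower expression of these markers within macrophages at the higher dose was not tested.

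For each of the 9 counts of genes, 100 splits of the arrays of the contrast into groups of the same sizes were tried in a fit of those arrays alone, and 1 of the 100, the real one, gave as many genes. The real value and the highest of the other splits were 3298 and 1 for 8 µM and 3257 and 1 for 200 µM at 24 h, 2883 and 1 for 8 µM and 2761 and 1 for 200 µM at 48 h. They were 647 and 1, and 805 and 2, for 200 µM against 8 µM at 24 h and 48 h, and 342 and 0 for the vehicle groups. For changes of effect over time residuals were permuted. They hold no signal level for the variance trend, so the real values are 133 and 123 in place of 205 and 176. The highest others were 2 at 8 µM and 1 at 200 µM. Chance is argued against for the counts of these fits only.

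Further values that lie far from the other 4 arrays of their group are given without explanation. Chance alone sets about 1 in 20 groups apart in this way, and it was seen in 6 of 36 groups of array measures, 16 of 192 of list means and 105 of 1128 of named genes, where 48 h vehicle replicate 4 was the one apart in 45 of its 188. That array had a median signal of 765, a 10th percentile of 85.7, 73.9% of probe sets above the filter and a median correlation of 0.896 with its group. A correlation of 0.973 for 200 µM 24 h replicate 5 and a 3′ to 5′ ratio of GAPDH of 1.20 for 200 µM 24 h replicate 2 also stood apart.

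List means in log2 that stood apart in 48 h vehicle replicate 4 were peroxisome biogenesis (11.27), fatty acid uptake (11.73), cholesterol synthesis (12.53), lipoproteins (13.16), ER stress and amino acid response (12.61), the respiratory chain (13.57), acute phase proteins (14.76), complement and coagulation (12.87), and dedifferentiation and matrix (12.89). In other arrays they were thioesterases in 8 µM 24 h replicate 1 (13.35) and 8 µM 48 h replicate 5 (13.67), lipogenesis in 200 µM 24 h replicate 1 (12.19), bile acid genes in 24 h vehicle replicate 1 (12.20), xenobiotic cytochromes P450 in 200 µM 24 h replicate 3 (13.02), complement and coagulation in 8 µM 24 h replicate 5 (13.08) and inflammatory signalling in 200 µM 48 h replicate 3 (9.55).

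Signals that stood apart in 48 h vehicle replicate 4 were those of Entpd1 (84.7), Krt79 (82.1), Ccn2 (14532.5), Hao2 (4460.4), Eva1c (41.5), Sgsm2 (172), Vim (8908) and Il1r2 (3260.3). In 24 h vehicle wells they were Ehhadh (889), Diaph3 (1149) and Slc25a34 (77.8) in replicate 1, Xpnpep2 (159) in replicate 2 and Krt79 (26.2) in replicate 4. At 8 µM and 24 h they were Npy in replicate 1 (3283), Hao2 in replicate 3 (519) and Lrrc39 in replicate 5 (2290.4), and at 8 µM and 48 h Slc25a34 in replicate 4 (242) and Vim in replicate 5 (2142). At 200 µM they were Calml4 (65.3) in 24 h replicate 3, Abca8a (195) in 24 h replicate 5, Slc25a34 (231) in 48 h replicate 3 and Cyp4a1 (66144) in 48 h replicate 5. Among the other named genes, 37 stood apart in 48 h vehicle replicate 4 and 46 in another array.

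The effect of WY-14643 differed between 48 h and 24 h by a test of the difference itself in 335 genes at 8 µM. They included Mapk13 (2.21), Dbp (2.17), Ppm1j (1.76), Eno2 (1.67), Pla2g4b (1.61), Spata19 (-3.09), Il1r2 (-2.998), Trim66 (-2.75), Prr15l (-2.39) and Cyp2c11 (-2.11), and the median of the lipogenic genes was 0.40. At 200 µM it differed in 278, among them Dbp (1.53), Fabp1 (1.41), Fads2 (1.27), Scd2 (1.25; its other probe sets did not pass), Spc24 (1.23), Bcl2l15 (-2.49), Pdzk1ip1 (-2.46), Il1r2 (-2.42), Npy (-2.17) and Poll (-1.80), and the lipogenic median was 0.33. Probe sets without a listed gene, which no gene-level comparison used, changed as well: 704 and 1046 at 8 µM and 630 and 917 at 200 µM, at 24 h and 48 h.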

How the results depend on the processing

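The 4 refits without 48 h vehicle replicate 4 were chosen after the results were seen, and all other alternatives were planned. No correlation, no named gene that passed and no called list of the treated and dose contrasts reversed under any alternative. Without 48 h vehicle replicate 4 the balance of rises and falls did turn for the changes over time and the vehicle, as given above. Each of the 9 counts of genes stayed within 1.5 times its value under pseudocounts of 1 and 64, no filter, a stricter filter, the mean of a gene's probe sets, probe sets, a block for each run of 6 arrays and no variance trend. Arrays limit what can be called by signal over background.

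Asking for a fold change of at least 1.5 as well leaves fewer genes by construction: 1031 and 915 (8 µM and 200 µM, 24 h), 1637 and 1396 (48 h), 54 and 110 (200 µM against 8 µM, 24 h and 48 h), 147 and 112 (change over time at 8 µM and 200 µM) and 278 (vehicle). Median centring gave 1462 and 1355 at 24 h, 39 and 96 between the doses, 42 and 28 over time and 300.0 for the vehicle. Besides the medians of all genes given above, it moves those of both changes over time to 0.147 log2. It kept 49.7%, 46.6%, 61.5% and 60.5% of the calls of the treated contrasts, quantile normalization 92.8%, 92.6%, 87.5% and 88.9%. Quantile normalization gave 541 and 450 over time, and after leaving out 48 h vehicle replicate 4 671 and 572, with 736 and 1091 between the doses. Array weights gave 750 and 1146 between the doses and 596 and 528 over time. Fits of fewer arrays, those of 1 time or of only the groups compared, gave 594 and 263 between the doses, 205 and 176 over time and 342 for the vehicle.

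Leaving out each array in turn gave 244 to 676 and 398 to 1037 genes between the doses at 24 h and 48 h, 250.0 to 582 over time at 8 µM and 199 to 488 at 200 µM. The highest of each came without 48 h vehicle replicate 4, and the lowest without 8 µM 24 h replicate 5, 200 µM 48 h replicate 3, 8 µM 24 h replicate 2 and 200 µM 48 h replicate 1. Camera with an estimated correlation called 33 of 144 list shifts, and 55 shifts without 48 h vehicle replicate 4. With different vehicle arrays for each dose the correlation of the doses averaged 0.701 at 24 h and 0.643 at 48 h, where 0.870 and 0.896 came with shared ones, which by construction raise it. The cause of changes other than the medians moved by median centring was not tested. Of 618 results for named genes 9 no longer passed with quantile normalization, 74 with median centring, 13 as the mean of a gene's probe sets and at most 12 under each other alternative apart from single arrays left out, and of 192 for lists of the treated and dose contrasts 6 and 12 with the 2 scalings and 18 with fry, 16 of these between the doses.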

Other observations

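The counts without 48 h vehicle replicate 4 are tests chosen after the result was seen. Xenobiotic cytochromes P450 held members that moved both ways and were not called as a list by camera in the treated contrasts. Among 21 genes 3, 4, 4 and 6 rose and 5, 4, 9 and 6 fell at 8 µM and 24 h, 200 µM and 24 h, 8 µM and 48 h, and 200 µM and 48 h (adjusted p = 0.53, 0.88, 0.12 and 0.88). Cyp1a1, which oxidises aromatic hydrocarbons, was at -1.497 (adjusted p = 5.7e-15) and -1.19 (adjusted p = 1.2e-12) at 8 µM, at 24 h and 48 h, and Cyp1a2 at -0.72 (adjusted p = 8.9e-09) and -1.74 (adjusted p = 2.2e-18). Cyp2c11 was at -2.96 (adjusted p = 1.3e-17) and -1.68 (adjusted p = 3.3e-11) at 8 µM and 200 µM at 48 h. The ethanol-oxidising Cyp2e1 went the other way, at 0.54 (adjusted p = 3.8e-04) and 1.83 (adjusted p = 1.3e-14). Conjugation and drug transport was split as well: of 23 genes 7, 5, 7 and 8 rose and 8, 8, 8 and 8 fell (adjusted p = 0.79, 0.78, 0.63 and 0.59). The carboxylesterase Ces1d was at 2.37 (adjusted p = 4.6e-18) at 8 µM and 48 h and the sulfotransferase Sult1c3 at 3.06 (adjusted p = 3.2e-16), and the glucuronosyltransferases Ugt2b1 and Ugt2b35 at -2.44 (adjusted p = 2.3e-17) and -1.14 (adjusted p = 4.7e-14). Of 19 lipoprotein genes 4, 3, 6 and 4 rose and 3, 3, 5 and 3 fell (adjusted p = 0.96, 0.7, 0.78 and 0.64). Lipoprotein lipase Lpl was at 1.28 (adjusted p = 3.1e-06) at 200 µM and 48 h and Mttp, which loads lipid onto apolipoprotein B, at 1.13 (adjusted p = 6.5e-13), against -2.31 (adjusted p = 2.8e-21) for Apoa5 and -1.37 (adjusted p = 5.0e-14) for Lcat. Without 48 h vehicle replicate 4, 5 and 9 lipoprotein genes fell at 8 µM and 24 h and at 200 µM and 48 h.

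The lists of oxidative stress, p53, the cell cycle and interferon did not pass with camera in any treated contrast either. Of 20 genes of the oxidative stress response 3, 2, 7 and 5 rose and 4, 5, 3 and 3 fell, in the order of contrasts used above (adjusted p = 0.48, 0.18, 0.095 and 0.43). Gclc, the enzyme that limits glutathione synthesis, was at -0.70 (adjusted p = 1.1e-09) at 200 µM and 24 h, and Pgd, of the pentose phosphate pathway, at 0.56 (adjusted p = 3.6e-08) at 8 µM and 48 h. Of 13 p53 and DNA damage genes 4, 3, 4 and 4 rose and 6, 5, 6 and 5 fell (adjusted p = 0.22, 0.3, 0.22 and 0.48). Sesn1 was at -1.28 (adjusted p = 1.0e-13), Gadd45b at -1.11 (adjusted p = 2.4e-13) and Cdkn1a at -0.51 (adjusted p = 1.4e-10) at 200 µM and 48 h. Of 21 cell cycle genes 4, 5, 6 and 7 rose and 0, 0, 1 and 0 fell (adjusted p = 0.19, 0.073, 0.31 and 0.2). The replication clamp Pcna was at 0.44 (adjusted p = 9.8e-06) at 200 µM and 48 h and Ccnd1 at 1.12 (adjusted p = 3.9e-04). Of 15 interferon response genes 0, 1, 0 and 1 rose and 2, 1, 7 and 4 fell (adjusted p = 0.79, 0.57, 0.064 and 0.65). Rsad2 was at 0.86 (adjusted p = 7.1e-05) at 200 µM and 24 h. Without 48 h vehicle replicate 4, 3 interferon genes rose at 200 µM and 24 h and 2 fell at 200 µM and 48 h, where 5 oxidative stress genes fell.

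Fry, which asks whether the members of a list changed without comparing them with other genes, called some of these lists, and ended 18 calls of camera in the treated and dose contrasts. It called the p53 list down in the 4 treated contrasts, in the same order (adjusted p = 3.2e-08, 1.1e-05, 9.4e-10 and 9.7e-08), although at 200 µM and 48 h its median was 0.11 and its mean -0.12. It called the cell cycle up except at 8 µM and 48 h (adjusted p = 0.039, 0.0033 and 0.020 in the others). At 8 µM and 48 h it called xenobiotic cytochromes P450 (adjusted p = 1.3e-04), the oxidative stress response (adjusted p = 0.026) and interferon genes (adjusted p = 0.0024), and at 200 µM and 48 h lipoproteins (adjusted p = 0.029). With camera the cell cycle passed at 200 µM and 24 h after median centring (adjusted p = 0.030). At 8 µM and 48 h interferon genes passed without 48 h vehicle replicate 2 (adjusted p = 0.034) or 5 (adjusted p = 0.041) and the oxidative stress response without replicate 2 (adjusted p = 0.035).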
